A study of Drosophila melanogaster with 36 samples.

How the data were processed

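The series profiled bacteria in the gut of female Drosophila melanogaster by sequencing amplicons of the bacterial 16S rRNA gene. Per the labels' protocols, the libraries of both mutant sets and of the RNAi set were made from pools of 30 adult midguts. For set 1 the labels conflict, since the source is given as the whole female animal while the tissue is given as intestine, so its shares are those of the gut only if the protocol holds. KDM5 is a histone demethylase, and kdm5 is its gene. The labels describe 36 libraries in 4 sets. Mutant set 1 held 5 kdm5 mutant and 5 w1118 libraries. Mutant set 2 held 5 and 5 libraries of the same genotypes, read on another sequencer. The mutant strain is labelled kdm5k6801/10424. An age of 1 to 3 days is given for the flies of set 1 and none for those of the other sets. Age may therefore differ between the mutant sets. Rearing at 25 C is given for all sets. The RNAi set held 5 libraries with the genotype Myo1A-Gal4TS/+;+/kdm5RNAi, where Myo1A-Gal4 drives expression in enterocytes, the absorptive cells of the gut, and 5 driver controls, Myo1A-Gal4TS/+. A feeding set compared kdm5 mutants given Lactobacillus plantarum with mutants on normal food, with 3 libraries each, after 2 days on vancomycin at 30 ug per mL and 3 days of feeding.

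The labels do not agree on the amplicon of mutant set 1. The sample protocol names primers 515F and 806R around region V4, while the text of the whole series names 338F and 806R, the pair of set 2, so it is not settled whether the primers of the mutant sets differed. The libraries of set 2 were amplified with 338F and 806R and read as pairs on a MiSeq, and the RNAi libraries covered V3 to V4 on a HiSeq, per the labels. Trimmomatic is named in the submitters' processing notes, with no version. The program that formed operational taxonomic units (OTUs, clusters of near-identical sequences), its identity threshold and the taxonomy database are not given in the sources used here.

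The authors deposited whole-number read counts per OTU for the libraries of 3 sets, with a taxonomy for each OTU. The deposited counts of set 1 covered 78 OTUs and added up to between 33962 and 75297 per library. The smallest total of an OTU was 58 counts over the 10 libraries, so rarer OTUs are absent from that table. The deposited counts of set 2 covered 107 OTUs, and every library added up to 21445, as after random subsampling to equal depth. The deposited counts of the RNAi set covered 50 OTUs, of which 2 had no count in any library, with 66813 to 69148 per library. For the feeding set, the deposited table used here lists 92 OTUs with a taxonomy and 1 fraction each, at least 0.81, which from its values is the confidence of the assignment. It holds no value per library, so the feeding comparison was not analysed here. A list of the representative sequences of the set 2 OTUs was also deposited by the authors.

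Counts were summed by genus, and OTUs with no genus name were kept under the next named rank. OTUs or genera with at least 10 counts in total and counted in at least 2 libraries were tested within each set with edgeR 4.0.16 (quasi-likelihood test, TMM normalization, R 4.3.3), with group as the only term and Benjamini-Hochberg adjustment at 0.05. Standard errors of log2 fold changes were derived from the F statistic. Shares are percent of all counts of a library. Shares, the Shannon index (natural log) and Bray-Curtis distances were compared with exact two-sided permutation tests over all 252 splits of 10 libraries, whose smallest p is 0.0079. Bray-Curtis distances were summarised as the R2 of a PERMANOVA. A set by genotype interaction was fitted in edgeR over the 20 libraries of both mutant sets, on the 22 genera present in both tables. Shares carry counting error: a count of 0 allows up to 3 counts of the library, 0.0139893% in set 2. A fold against a group at 0 in all libraries was computed against the mean of the shares worth 3 counts in each library and is given as a lower bound. Such limits cover counting error only, because PCR copies are not independent molecules.

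All shares are relative. The number of bacteria per gut was not used here, so a share can change because another taxon changed. TMM assumes that most taxa keep their level, which few-taxon communities do not guarantee. The log2 fold change of a genus with TMM minus that with total counts alone had a median over genera of 1.51 in set 1, 0.03 in set 2 and 0.56 in the RNAi set, so fitted fold changes are relative to that shift and the shares are given beside them. The TMM factors at genus level also varied within groups, from 0.257 to 1.88 in the set 1 mutants. In set 2, w1118 replicate 2 had 1.85, and the other w1118 libraries had 0.871 to 0.910.

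The alternatives were DESeq2 1.42.0 with poscounts size factors, total counts without TMM, no low-count filter, removal of Wolbachia, chloroplast and mitochondria counts, other scales, rarefaction with 100 draws, the replicate number as a block, and leaving out each library in turn. They were chosen before the data were examined, as were the groups, tests and taxon lists. A restriction to taxa with a mean share of at least 0.1%, the alternatives of the list shares, the phyla of set 1 without an OTU block, and the interaction, the folds with their limits and the distances within groups without each library in turn were added after seeing the data. The fit was tested on simulated counts drawn with the real means and library sizes, with 4-fold and 16-fold changes and a dispersion of 0.1. Among the 77 OTUs of set 1, where 20 changed, it recovered 89% of the 4-fold and 98% of the 16-fold changes, with 1.49% of unchanged OTUs called. For the 29 OTUs of set 2, with 14 changed, it recovered 61.4% and 88.6%, with 7% of unchanged OTUs called. For the 46 OTUs of the RNAi set, with 20 changed, it recovered 87% and 97.5%, with 3.85% called. With changes only in taxa under 1%, 4.41% of unchanged set 2 OTUs were called. The dispersion was fixed and not taken from the data. In set 1, 68 of 77 OTUs were called, far more than were changed in the simulation, so these rates need not hold for the real libraries.

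The taxa named in the text follow a rule: genera of the lactic, acetic, enteric and endosymbiont lists with a mean share of at least 1% in either group, the 5 most abundant genera, up to 8 OTUs or genera per direction with the largest fold change among those past the threshold, the most abundant Lactobacillus OTU with every OTU assigned to L. plantarum, and phyla of at least 1%. Other taxa named as members of a list, or as an OTU block, were chosen after their values were seen. The 7 taxon lists held lactic acid bacteria, acetic acid bacteria, enteric and opportunist bacteria, endosymbionts, organelles, reagent-associated genera and vertebrate gut anaerobes. No Wolbachia or Spiroplasma OTU was listed in any of the 3 tables. No organelle OTU was listed in set 1. Set 2 and the RNAi set each listed 1 organelle OTU. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and biopython 1.88.

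No pair of replicate libraries agreed within sampling noise. The chi-square per degree of freedom of 20 pairs per set had a median of 179 in set 1, 23.5 in set 2 and 6.94 in the RNAi set, so each library was counted once. The labels do not say whether replicates came from separate fly cultures, so p-values measure the spread between these libraries.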

Results

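Bacterial communities of the fly gut were compared between kdm5 mutants and w1118 flies in 2 separately sequenced sets, and between flies with kdm5 RNAi in enterocytes and driver controls in another. Each group had 5 libraries. The library totals ranged from 33962 to 75297 counts in set 1, were 21445 in each library of set 2, and ranged from 66813 to 69148 in the RNAi set. Values are percent of the counts of a library, as mean ± SD.

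The first comparison asked how the gut community of kdm5 mutants differed from that of w1118 flies in set 1. An unnamed genus of Orbaceae, a family of insect gut bacteria, made up 66.7% ± 27.3 (SD, n = 5) of counts in w1118 and 0.319% ± 0.229 (n = 5) in the mutants. Morganella, an enteric genus that includes opportunists, made up 39.1% ± 15.3 (n = 5) in the mutants and 0.00170% ± 0.00185 (n = 5) in w1118. Acetobacter, a genus of acetic acid bacteria common in flies, was higher in the mutants at 45.8% ± 9.20 (n = 5) against 15.7% ± 8.43 (n = 5). Gluconobacter, another acetic acid bacterium, rose from 0.0581% ± 0.111 (n = 5) to 10.6% ± 9.23 (n = 5). For each of these 4 genera the exact permutation p was 0.0079, the smallest that 5 against 5 libraries allow (0.0102 adjusted over all genera). Without w1118 replicate 4 the Gluconobacter share of w1118 was 0.00859%, and without w1118 replicate 5 that of Morganella was 0.00105%. In edgeR's quasi-likelihood test the adjusted p was 1.89e-05 for Orbaceae, 9.13e-08 for Morganella, 0.0013 for Acetobacter and 0.000276 for Gluconobacter. When only taxa of at least 0.1% were fitted, Acetobacter was not called (adjusted p = 0.342).

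Commensalibacter, an acetic acid bacterium of the fly gut, had a share of 1.73% ± 0.980 (n = 5) in the set 1 mutants and 14.5% ± 25.7 (n = 5) in w1118. That difference did not exceed the replicate spread (exact permutation p = 0.1667), and w1118 replicate 4 alone held 60.3%, without which the w1118 mean was 3.04%. Its edgeR adjusted p was 0.125 with TMM and 0.0175 with total counts only. Lactobacillus made up 0.0790% ± 0.0325 (n = 5) in the mutants and 0.129% ± 0.103 (n = 5) in w1118, which the exact permutation test did not separate (p = 0.3175). The sign of its fitted log2 change depended on the scaling, at 1.04 with TMM and -0.71 with total counts only. The most abundant Lactobacillus OTU of set 1 had shares of 0.0788% ± 0.0327 and 0.0933% ± 0.102 (n = 5 each, exact permutation p = 0.8016), and without w1118 replicate 2 the w1118 share was 0.0566%, below that of the mutants.

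Among the lists fixed beforehand, enteric and opportunist bacteria rose from 0.372% ± 0.317 to 39.6% ± 15.4 (n = 5 each, adjusted exact permutation p = 0.0132), and without w1118 replicate 5 the w1118 share was 0.236%. Of its 3 tested genera 2 were higher, both over all genera and adjusted over the list alone. These were Morganella and Pectobacterium, and the latter, at 0.389% against 0.230% (0.142% without w1118 replicate 5), was separated by edgeR (adjusted p = 0.00744) but not by the exact permutation test (p = 0.3254). Lactic acid bacteria fell from 0.470% ± 0.0802 to 0.157% ± 0.119 (n = 5 each, adjusted exact permutation p = 0.0132). Of the 4 genera tested there, 2 were lower over all genera and adjusted over the list alone, and these were Enterococcus, from 0.141% to 0.000833%, and Streptococcus, from 0.0884% to 0.000855%. Without mutant replicate 2 the mutant share of Enterococcus was 0.000343%. Of the list's OTUs 5 belonged to a block of OTUs counted almost only in w1118, and with these left out the list was at 0.155% ± 0.120 and 0.206% ± 0.145 (n = 5 each, exact permutation p = 0.5079). Acetic acid bacteria held 58.1% ± 15.3 in the mutants and 30.3% ± 27.8 in w1118 (n = 5 each, adjusted exact permutation p = 0.0992), and without w1118 replicate 4 the list passed (p = 0.0198). Of its 3 genera 2 were higher over all genera and adjusted over the list alone.

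Some low-abundance genera of set 1 were counted only or almost only in 1 group. Others, such as Lactobacillus and Pectobacterium, were counted in all 5 libraries of both groups and were not separated by the exact permutation test. All 5 tested genera of the vertebrate gut anaerobe list were lower in the mutants, over all genera and adjusted over the list alone, and the list fell from 0.265% ± 0.113 to 0.000539% ± 0.00121 (n = 5 each, adjusted exact permutation p = 0.0132), with all mutant counts in replicate 1. Faecalibacterium, a gut anaerobe of mammals, had no count in the mutants and 0.0377% ± 0.0128 in w1118, at least 7.79-fold lower. Collinsella was at least 7.60-fold lower, Intestinimonas at least 7.00-fold, Intestinibacter at least 6.07-fold, Megamonas at least 5.61-fold, Lachnoclostridium at least 5.48-fold and unnamed Ruminococcaceae at least 14.7-fold. Paracoccus was also at 0 in the mutants (at least 12.3-fold lower by its mean), but the exact permutation test did not separate it (p = 0.4444). It was counted in 2 w1118 libraries, and without replicate 3 its mean there was 0.00294%, below the share worth 3 counts in the mutants, so no fold remained. In the other direction, Sphingomonas rose from 0.00239% to 0.338% ± 0.0276, Luteibacter from 0.000433% to 0.205% ± 0.0213 and unnamed Xanthobacteraceae from 0.000306% to 0.0853% ± 0.0186 (n = 5). Without w1118 replicate 4 the Sphingomonas share of w1118 was 0.000780%. Luteibacter and unnamed Xanthobacteraceae were each counted in 1 w1118 library only, replicate 5 and replicate 2, and were at 0 in w1118 without it. Unnamed Acetobacteraceae was at least 51.9-fold higher (32.6-fold without mutant replicate 1), Terriglobus at least 6.76-fold and unnamed Micropepsaceae at least 4.43-fold. The reagent-associated list, which holds Sphingomonas, was at 0.473% ± 0.0437 and 0.555% ± 0.293 (n = 5 each, adjusted exact permutation p = 0.6111), with 4 of its 8 genera higher and 3 lower, both over all genera and adjusted over the list alone.

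In all, edgeR called 47 of 54 genera in set 1, 18 higher and 29 lower in the mutants, and 68 of 77 OTUs, 26 higher and 42 lower. With total counts only it called 48 genera, 15 higher and 33 lower, and 69 OTUs, 23 higher and 46 lower. The balance of directions thus depended in part on the scaling. The OTUs with the largest fold changes were, in the mutants, OTU28 (Morganella), OTU50 (Acetobacteraceae), OTU11 and OTU19 (Sphingomonas), OTU12 (Rhizobiaceae), OTU76 (Luteibacter), OTU26 (Xanthobacteraceae) and OTU45 (Terriglobus), and in w1118 OTU22 (Ruminococcaceae), OTU24 (Collinsella), OTU77 (Faecalibacterium), OTU33 (Streptococcus), OTU31 (Intestinimonas), OTU38 (Lachnospiraceae), OTU73 (Blautia) and OTU40 (Intestinibacter). Among taxa of at least 0.1%, 13 of 19 genera and 12 of 18 OTUs were called. Firmicutes fell from 1.54% ± 0.372 to 0.162% ± 0.117 and Proteobacteria rose from 98.3% ± 0.416 to 99.8% ± 0.109 (n = 5 each, exact permutation p = 0.0079, also after adjustment over phyla). Most of that difference lay in the block of 35 OTUs counted almost only in w1118, of which 27 were Firmicutes. With the block left out of the counts, Firmicutes were at 0.421% ± 0.160 in w1118 and 0.157% ± 0.119 in the mutants, and Proteobacteria at 99.6% ± 0.160 and 99.8% ± 0.112 (n = 5 each, exact permutation p = 0.0317 for both, not adjusted). The Shannon index was higher in the mutants, 1.17 ± 0.0884 against 0.859 ± 0.228 (n = 5 each, exact permutation p = 0.0238). Group accounted for an R2 of 0.759 of the Bray-Curtis distances (exact permutation p = 0.0079).

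**Figure D1:**
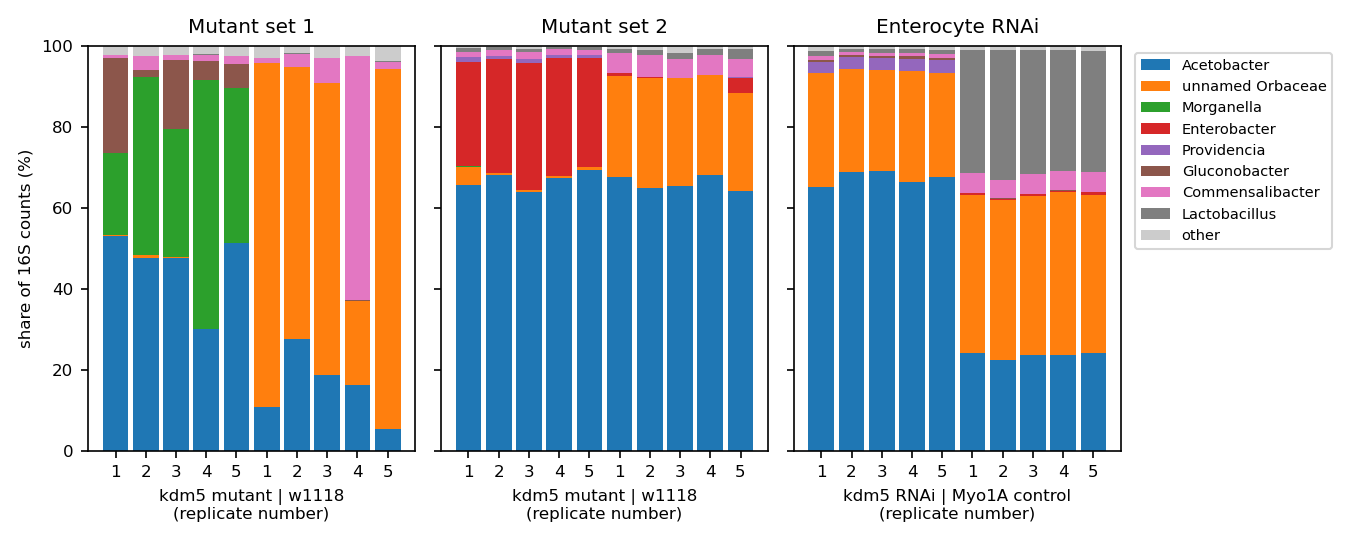
Stacked bars show the share of 16S counts (percent) of 8 genera and of all other taxa in each library, with the replicate number on the horizontal axis, for mutant set 1, mutant set 2 and the RNAi set. Orbaceae made up 66.7% of w1118 counts in set 1 and 25.5% in set 2, and Lactobacillus made up 30.5% in the RNAi controls.

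Set 2 compared the same genotypes in separately made libraries, read on another sequencer. Enterobacter, an enteric genus, rose from 0.911% ± 1.58 in w1118 to 28.2% ± 2.17 in the mutants (n = 5 each), and Providencia, an enteric genus with fly pathogens, from 0.0224% ± 0.0423 to 0.948% ± 0.257. Unnamed Orbaceae fell from 25.5% ± 1.33 to 1.31% ± 1.70, and Commensalibacter from 4.93% ± 0.448 to 1.41% ± 0.292. Lactobacillus was 2.26-fold lower in the mutants, at 0.698% ± 0.192 against 1.57% ± 0.542 (n = 5 each). Leuconostoc, another lactic acid bacterium, fell from 0.406% ± 0.121 to 0.119% ± 0.0775. Unnamed Enterobacteriaceae rose from 0.00280% ± 0.00626 to 0.198% ± 0.186. The exact permutation p was 0.0079 for each of these 7 genera and 0.0863 after adjustment over all 87 listed genera. The exact test alone thus separated none of them once adjusted. That adjustment included genera too rare for the edgeR test, which adjusted over 27. Since 0.0079 is the smallest p possible, the result partly reflects the number of genera listed. Acetobacter, at 66.8% ± 2.15 and 66.0% ± 1.74 (n = 5 each), was not separated before adjustment (exact permutation p = 0.5079). Single libraries weighed on these means: without w1118 replicate 5 the w1118 shares were 0.213% for Enterobacter, 0.00350% for Providencia and 0 for unnamed Enterobacteriaceae, without mutant replicate 1 the mutant share of Orbaceae was 0.553%, and without mutant replicate 3 that of unnamed Enterobacteriaceae was 0.120%.

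The edgeR adjusted p values were 0.000541 for Orbaceae, 0.00353 for Commensalibacter, 0.00519 for Providencia and unnamed Enterobacteriaceae, 0.0198 for Enterobacter and 0.0492 for Lactobacillus and Leuconostoc. The Lactobacillus call was lost with DESeq2 (adjusted p = 0.517) and in 8 of the 10 fits that left out 1 library, as was that of Leuconostoc (adjusted p = 0.43 with DESeq2), and the Enterobacter call was lost without w1118 replicate 1 (adjusted p = 0.0571). With no low-count filter, Commensalibacter, Lactobacillus and Leuconostoc were not called. In total edgeR called 7 of 27 genera, 3 higher and 4 lower, and 9 of 29 OTUs, 3 higher and 6 lower. Without w1118 replicate 1 it called 4 genera, and without w1118 replicate 3 it called 8. Of the called OTUs 7 belonged to the called genera, and these were OTU18 (Enterobacter), OTU105 (Providencia), OTU91 (unnamed Enterobacteriaceae), OTU48 (Orbaceae), OTU90 (Commensalibacter), OTU83 (Leuconostoc) and OTU16 (Lactobacillus), the most abundant Lactobacillus OTU. Of the other two, OTU82 (Corynebacterium) had no count in the mutants and was at least 1.73-fold lower, and OTU5 (Mucilaginibacter) was at 0.00373% in the mutants (0.00233% without mutant replicate 5) and 0.0215% in w1118. With 1 library left out, the call of OTU5 was lost in 6 of 10 fits, of OTU16 in 5, of OTU83 in 2 and of OTU90 in 1, and those of OTU5, OTU16 and OTU83 were lost with DESeq2 and those of these 3 and OTU82 with no low-count filter.

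By list, enteric and opportunist bacteria rose in set 2 from 1.03% ± 1.61 to 29.2% ± 1.98, with 2 of 5 genera higher, and lactic acid bacteria fell from 1.98% ± 0.641 to 0.824% ± 0.179, with 2 of 2 genera lower (n = 5 each, adjusted exact permutation p = 0.0238 for both). Without w1118 replicate 5 the enteric list was at 0.317% in w1118. Acetic acid bacteria held 68.2% ± 1.94 and 70.9% ± 1.85 (n = 5 each, adjusted exact permutation p = 0.1587), with 1 of 2 genera lower. These counts were the same over all genera and adjusted over the list alone. Reagent-associated genera (0.0867% and 0.137%), vertebrate gut anaerobes (0 and 0.00839%) and organelles (0.000933% and 0) were not separated, with adjusted exact permutation p of 0.2000, 0.2000 and 1.0000. Firmicutes were at 2.01% ± 0.625 in w1118 and 0.856% ± 0.153 in the mutants, and Proteobacteria at 97.6% ± 0.699 and 99.1% ± 0.131 (n = 5 each, exact permutation p = 0.0079 for both, 0.0595 after adjustment over phyla). The Shannon index, 0.858 ± 0.0740 against 0.945 ± 0.0653 (n = 5 each), was not separated (exact permutation p = 0.1032) but was without mutant replicate 1 (p = 0.0238). The Bray-Curtis R2 was 0.967 (exact permutation p = 0.0079).

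The genotype effect was compared between sets 1 and 2 on the 22 genera listed in both, with unnamed genera matched by family name only. It differed for 9 genera in the edgeR interaction test with TMM. With total counts only it differed for 10, and the added genus was Acetobacter. Its log2 difference was then -1.52 (adjusted p = 0.0195, against 0.216 with TMM). Most of the 9 genera have OTUs in the blocks counted almost only in w1118 or almost only in mutants of set 1. Orbaceae, which is in neither block, was among the 9. Its shares were 209-fold lower in the mutants of set 1 and 19.4-fold lower in set 2 (interaction log2 difference 3.94, adjusted p = 0.0039). With total counts only the difference was 3.43 (adjusted p = 0.00284). In the separate TMM fits the log2 changes of Orbaceae were -5.80 in set 1 and -4.43 in set 2. The size of the difference thus depends on the scaling. Without mutant replicate 1 of set 2 the Orbaceae fold in set 2 was 46.2 and the interaction 2.33 (adjusted p = 0.0128). Without w1118 replicate 2 of set 2 the difference was no longer called (2.65, adjusted p = 0.0798).

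The RNAi set asked how the gut community with kdm5 RNAi in enterocytes differed from that of driver controls. The level of kdm5 was not used here, so how far the RNAi lowered it is not known. Lactobacillus made up 30.5% ± 0.918 of counts in the driver controls and 1.00% ± 0.181 with kdm5 RNAi (n = 5 each), 30.4-fold lower. Almost all of it was OTU3, the one OTU assigned to L. plantarum, at 30.5% ± 0.918 and 1.00% ± 0.181. Acetobacter rose from 23.6% ± 0.679 to 67.3% ± 1.64, Gluconobacter from 0.0244% ± 0.0111 to 0.511% ± 0.0215, and Providencia from 0 counts in the controls to 2.96% ± 0.150, at least 664-fold higher. Commensalibacter fell from 4.84% ± 0.235 to 0.854% ± 0.0824, Enterobacter from 0.484% ± 0.0949 to 0.0595% ± 0.0174 and Massilia from 0.0178% ± 0.00764 to 0.000581%, while Leuconostoc fell from 0.138% ± 0.0129 to 0 counts, at least 31.5-fold lower. Unnamed Orbaceae made up 39.3% ± 0.483 in the controls and 26.3% ± 1.31 with RNAi. For all of these the exact permutation p was 0.0079 (n = 5 each), or 0.0353 after adjustment over all genera. Without RNAi replicate 1 or 4, Massilia with RNAi was at 0.000364% or 0.000362%.

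In edgeR the adjusted p was 4.23e-13 for Lactobacillus and Acetobacter, 6.45e-12 for Commensalibacter and 3.09e-12 for Providencia. Orbaceae was not called with TMM (log2 change -0.01, adjusted p = 0.687) but was with total counts only (log2 change -0.58, adjusted p = 3.52e-09). The median shift by TMM in this set, 0.56, is close to that change, so the TMM value is no evidence that Orbaceae stayed level. Acinetobacter (0.238% against 0.221%) and Brevibacterium (0.0738% against 0.0536%) were called higher with TMM, and neither was called with total counts only (adjusted p = 0.726 and 0.331). In total edgeR called 10 of 39 genera, 5 higher and 5 lower, and 9 with total counts only, 3 higher and 6 lower. Of 46 OTUs 9 were called, 3 higher, which were OTU1 (Acetobacter), OTU5 (Providencia) and OTU6 (Gluconobacter), and 6 lower, among them OTU3 (Lactobacillus), OTU4 (Commensalibacter), OTU7 (Enterobacter), OTU13 (Leuconostoc) and OTU44 (Massilia). OTU40 (Brevundimonas), at 0.00950% in the controls and 0.000293% with RNAi, was among the lower OTUs (adjusted p = 0.0438), and its RNAi counts were all in replicate 2. Its call was lost in 9 of the 10 fits that left out 1 library.

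By list, lactic acid bacteria fell from 30.6% ± 0.920 to 1.00% ± 0.181 with 2 of 2 genera lower, acetic acid bacteria rose from 28.5% ± 0.890 to 68.7% ± 1.57 with 2 of 3 genera higher and 1 lower, and enteric and opportunist bacteria rose from 0.719% ± 0.128 to 3.28% ± 0.155 (n = 5 each, adjusted exact permutation p = 0.0159 for each list). The enteric list had 1 genus higher and 1 lower of 5 over all genera, and 2 higher and 1 lower adjusted over the list alone, and the other lists had the same counts both ways. Reagent-associated genera (0.333% and 0.369%), organelles (0.0306% and 0.0339%) and vertebrate gut anaerobes (0.0105% and 0.0230%) were not separated, with adjusted exact permutation p of 0.4524, 0.8190 and 0.8889. Which group had more vertebrate gut anaerobes depended on control replicate 2, without which the controls were at 0.00520%. Firmicutes fell from 30.7% ± 0.973 to 1.04% ± 0.191 and Proteobacteria rose from 69.1% ± 0.979 to 98.7% ± 0.211 (n = 5 each, exact permutation p = 0.0079, or 0.0198 after adjustment over phyla). The Shannon index fell from 1.33 ± 0.0125 to 0.912 ± 0.0330 (n = 5 each, exact permutation p = 0.0079), and the Bray-Curtis R2 was 0.996 (exact permutation p = 0.0079).

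**Figure D2:**
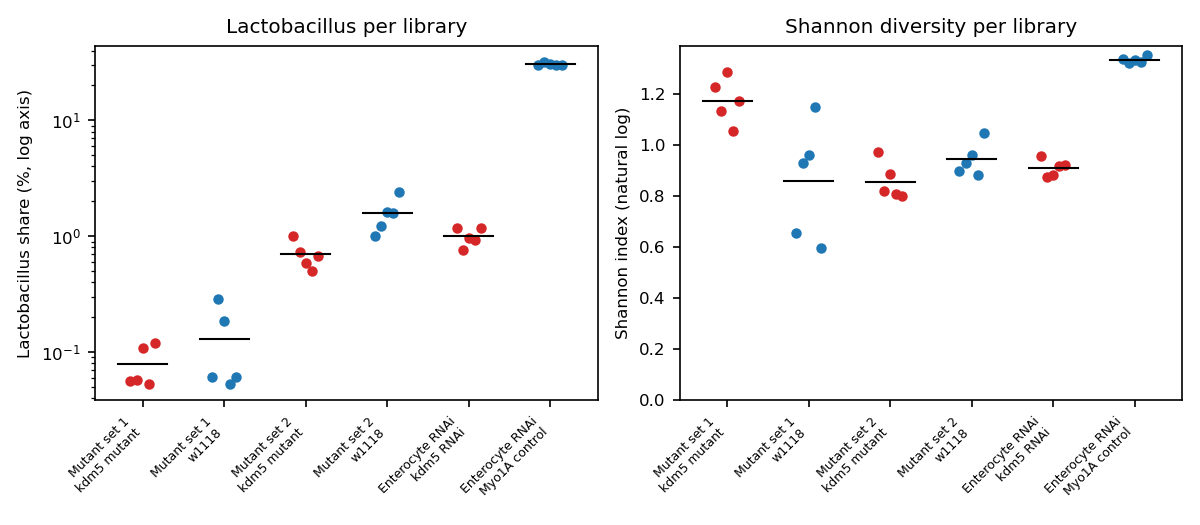
Points are single libraries and black lines group means, with the Lactobacillus share (percent, log axis) on the left and the Shannon index (natural log) on the right. Lactobacillus was 30.5% in the RNAi controls and 1.00% with kdm5 RNAi, and 1.57% and 0.698% in w1118 and mutants of set 2.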

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

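The sequence identity test and the counts of splits were planned before their values were seen. The tests of library size, of a single source and of rescaled shares were chosen only after the counts had been inspected, and the 13 OTUs tested apart were picked after the result for all 35 OTUs was known. Of 38 sets of 5 values examined, such as the shares of 1 genus in the libraries of 1 group, 7 had a library far from the others. Chance gives about 1 in 20 for independent sets. These were not independent, since the shares of a library add up to a fixed total and 1 library can be flagged for several genera. The number flagged is therefore no test against chance. In set 1, w1118 replicate 4 held 60.3% Commensalibacter (next library 6.09%) and 0.256% Gluconobacter (next 0.0179%), and mutant replicate 4 held 29.9% Acetobacter (next 47.4%). In set 2, mutant replicate 1 held 4.36% Orbaceae (next 0.625%), mutant replicate 3 held 1.93% Commensalibacter (next 1.37%) and w1118 replicate 5 held 3.70% Enterobacter (next 0.681%). In the RNAi set, control replicate 2 held 32.1% Lactobacillus (next 30.4%).

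The genotype effect of 9 genera differed between sets 1 and 2 in the edgeR interaction test with TMM. As log2 effect in set 2 minus set 1, the differences were -16.55 for unnamed Acetobacteraceae, -8.62 for Sphingomonas, -8.18 for Sphingobium, 10.89 for Streptococcus, 9.91 for Turicibacter, 8.83 for Staphylococcus, 4.14 for unnamed Enterobacteriaceae, 3.94 for Orbaceae and 3.31 for Acinetobacter, with adjusted p between 0.000218 and 0.0176. Without w1118 replicate 2 of set 2, Orbaceae (2.65, adjusted p = 0.0798), unnamed Enterobacteriaceae, Acinetobacter and Sphingobium were not called. Several differences rest on single libraries of set 2: unnamed Acetobacteraceae was counted there in 1 w1118 library, Turicibacter in 1 mutant library and Sphingobium in 1 of each, and each call was lost without such a library. Unnamed genera were matched by family name only. The unnamed Enterobacteriaceae OTU of set 1 is assigned to Escherichia coli, while set 2 lists Escherichia-Shigella apart from its unnamed OTU, so by these names the 4.14 compares different bacteria and is no difference in the effect on 1 genus. Fitted values of genera near 0 counts in a group are not bounds. In set 1, all OTUs of Streptococcus, Turicibacter, Staphylococcus, Sphingobium and unnamed Acetobacteraceae belong to the group-only blocks described below. So do some OTUs of Sphingomonas and Acinetobacter. The differences of these genera therefore share the open origin of the blocks.

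In set 1, 35 OTUs were counted in all 5 w1118 libraries with at most 3 counts in all mutant libraries together, and 15 showed the opposite. The w1118 block summed to between 1.09% and 1.95% of counts. Of the 15 mutant OTUs, 6 were of the reagent-associated list and 14 were Proteobacteria, while 2 of the 35 w1118 OTUs were of that list. Library size is argued against by the totals of the groups, which the choice of OTUs does not set. The ratio that depth would need, and its limit, do come from the counts by which the OTUs were picked. That ratio therefore had to be small. For depth alone to remove the w1118 OTUs, the mutant total would have to be 0.00561 of the w1118 total (upper 95% limit 0.00842), but it was 1.17 times as large. For the mutant OTUs the w1118 total would have to be 0.00164 of the mutant total (upper limit 0.00357), but it was 0.852. A single foreign source would hold its OTUs in fixed ratios. Over all 35 OTUs that was not so (chi-square per degree of freedom 13.8). For the 13 Ruminococcaceae and Lachnospiraceae OTUs the ratios were constant within counting error (1.30), while the 5 most abundant w1118 genera gave 7928. This measure grows with counts, and the 13 OTUs held only 1399, so these values differ in power. Foreign DNA from 1 source in the w1118 libraries may explain those 13 OTUs. The 15 mutant OTUs gave 10.4, so their ratios were not fixed either, and reagent DNA as their origin was not tested. A genotype effect stays open and untested, as does an extraction batch that followed the groups, since the labels give none.

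In percentage points, the enteric genus that rose most was Morganella in set 1 and Enterobacter in set 2. Morganella in set 2 was counted in 1 mutant library only (group mean 0.0578%) and in no w1118 library. The edgeR interaction test did not call it (adjusted p = 0.955), but with a standard error of 112 that test could not decide. A misnamed Enterobacter OTU in set 2 was tested by sequence: it was 94.8% identical to the set 2 OTU named Morganella and 96.2% to that named Providencia, both under the 97% set beforehand, although Morganella and Providencia themselves shared 96.7%. The margin is small. These sequences represent separate OTUs of the same clustering, which keeps such sequences apart, so a low identity was largely set beforehand. The test therefore cannot decide whether the name Enterobacter is right. No sequence of the set 1 Morganella OTU was used here, so its name stays untested. A change of the resident enteric bacteria between the sets, which were made separately, stays open.

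In the RNAi set, the rise of Acetobacter was set against the loss of Lactobacillus counts, which raises every other share. With Lactobacillus counts left out, Acetobacter was still at 68.0% ± 1.59 against 34.0% ± 0.615 (n = 5 each, exact permutation p = 0.0079), a difference of 34.1 percentage points, which argues against rescaling by Lactobacillus alone. Orbaceae was then at 26.6% against 56.6%. Whether Acetobacter gained cells or Orbaceae lost them is open, since shares hold no total. An effect of the RNAi remains a candidate. It cannot be told apart here from a difference in cross, fly culture or batch between the groups. No control carried kdm5RNAi without the driver.

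The counts of called taxa were set against other splits of the same libraries. Those splits mix strongly separated groups, which widens the spread on each side, so they could hardly give many calls. They also cannot tell genotype from a difference in fly culture or batch. Among 100 splits of the 10 libraries of each set, only the real split (1 of 100) gave as many, with 68 OTUs and 47 genera in set 1 against 0 and 0 in the highest other split, 9 OTUs and 7 genera in set 2 against 0 and 1, and 9 OTUs and 10 genera in the RNAi set against 1 and 1.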

How the results depend on the processing

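The restriction to taxa of at least 0.1%, the alternatives of the list shares, the phyla without the w1118 block, and the interaction, the distances within groups and the limits of folds without each library were chosen after seeing the data. No feeding alternative was run, since the feeding comparison was not analysed here. The replicate numbers did not pair the libraries: same-numbered genus deviations correlated above 0.1 in 1 of 5 pairs in set 1, 0 in set 2 and 2 in the RNAi set, and 1, 0 and 1 libraries correlated best with their own number. With the replicate block the exact tests of 5 pairs reach no p below 0.0625, so they cannot pass: Bray-Curtis R2 stayed at 0.759, 0.967 and 0.996, Lactobacillus at -0.876 percentage points in set 2 and -29.5 in the RNAi set, and Shannon differences at 0.316 in set 1 (p = 0.1250) and -0.422 in the RNAi set, and 0 lists passed in each set, by the construction of that test. The block changed no count of called taxa by more than 1.5 times. It did end the calls of the genus Lactobacillus, OTU82, OTU5 and OTU16 in set 2 and of OTU40 in the RNAi set.

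Among taxa of at least 0.1%, 12 OTUs and 13 genera were called in set 1. Of the 19 genera tested there 15 were called in the fit of all genera, and 11 were called in both, with Acetobacter, Pectobacterium, unnamed Enterobacteriaceae and unnamed Rhizobiaceae lost and Commensalibacter and Leuconostoc gained. All the lost genera had been called higher in the fit of all genera. TMM was computed anew on the kept genera. The log2 change of Acetobacter went from 3.37 to 0.933 and that of Commensalibacter from -1.91 to -4.51, both toward lower values in the mutants. The lost Acetobacter call thus came with a shift that Commensalibacter shared. Whether the new TMM factors explain all the changed calls was not tested. Leaving out 1 library gave 4 to 8 called genera in set 2 and a Shannon difference of -0.116 to -0.0613 there (exact permutation p from 0.0238 to 0.2063), and 7 to 11 genera in the interaction test. With DESeq2, set 2 had 7 OTUs, 4 higher and 3 lower, and 6 genera, 4 higher and 2 lower, so the split changed. Removing the 1 organelle OTU in the RNAi set gave 11 OTUs, 5 higher and 6 lower. Removal of Wolbachia and organelles changed nothing in set 1, where none were listed, and says nothing there. Over the 73 named OTUs and genera, 1054 of 1135 alternative fits kept direction and side of the threshold, 64 lost a call, 8 gained one and 9 changed sign with no call in either fit. The log2 changes of opposite sign were 0.278 for Commensalibacter of set 1 with the replicate block, -0.251 with total counts and -0.0374 with no filter for OTU2 (Lactobacillus) of set 1, and 0.0297 for unnamed Orbaceae with RNAi among taxa of at least 0.1%. With 1 library left out, the log2 change ranged from -0.215 to 1.89 for OTU2, from -0.0323 to 0.664 for Acetobacter in set 2 and from -0.0270 to 0.000415 for unnamed Orbaceae with RNAi. Of the lost calls 47 were in set 2, which has the lowest depth and fewest counts per taxon.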

Other observations

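The comparisons below were made after the results were seen. Several genera moved alike in set 2 and with RNAi. Commensalibacter was lower in set 2 (3.49-fold) and with RNAi (5.67-fold), Providencia was higher in set 2 (42.3-fold) and with RNAi (at least 664-fold), and Leuconostoc was lower in set 2 (3.40-fold) and with RNAi (at least 31.5-fold). In set 1, Commensalibacter (exact permutation p = 0.1667) and Leuconostoc (0.0765% in the mutants and 0.112% in w1118, or 0.0476% without w1118 replicate 4, exact permutation p = 0.6270) were not separated. That does not set the mutant sets apart, since the interaction test called neither genus (adjusted p = 0.216 and 0.616). No Providencia OTU is listed in the set 1 table. Acetobacter and Gluconobacter instead moved alike in set 1 and with RNAi. Acetobacter was higher in set 1 (2.91-fold) and with RNAi (2.85-fold) but was not separated in set 2 (exact permutation p = 0.5079). Gluconobacter was higher in set 1 (182-fold, or 1232-fold without w1118 replicate 4) and with RNAi (20.9-fold). No Gluconobacter OTU is listed in the set 2 table. Enterobacter went opposite ways, 30.9-fold higher in the set 2 mutants and 8.14-fold lower with RNAi. Without w1118 replicate 5 the folds in set 2 were 132 for Enterobacter and 271 for Providencia. The difference between the mutant sets and the RNAi set was not tested.

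The feeding table lists 92 OTUs, of which 48 belong to Ruminococcaceae or Lachnospiraceae and 4 to Lactobacillus. These families hold 13 of 78 OTUs in set 1, 0 of 107 in set 2 and 1 of 50 in the RNAi set. Within set 1, the 13 OTUs took 0.757%, 0.459%, 0.251%, 0.289% and 0.630% of the counts of w1118 replicates 1 to 5.

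Libraries of a group differed far less in the RNAi set than in set 1. The mean Bray-Curtis distance within a group was 0.0238 for kdm5 RNAi and 0.0165 for its controls, 0.0428 and 0.0384 for mutants and w1118 of set 2, and 0.215 and 0.343 for mutants and w1118 of set 1. Without w1118 replicate 4 the last of these was 0.153, and without control replicate 2 the RNAi controls were at 0.0107.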
